A study of Mus musculus with 6 samples.

How the data were processed

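RNA extracted with a column kit from 6 samples of the mouse line IEC 4.1 was sequenced on the DNBSEQ platform, per the labels' protocols. There were 2 groups of 3 samples, untreated and given interferon-gamma at 10 ng/ml for 6 h, taken from the labels. Whether the replicates came from separate cultures is not given in the sources used here, so the p-values may measure technical spread. HISAT, HISAT2, mm10 and GRCm38.p6 are named per the submitters' processing notes, which give no roles, and the counting program is not given in the sources used here.

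Each sample had 1 table of 14701 genes, all typed as coding mRNA. Read counts were deposited as estimated counts, of which 6.8% to 7.37% per library were not whole numbers, as when reads are divided between similar genes. TPM values, deposited beside the counts per the file headers, scale each gene for length and library. FPKM values, also deposited per the file headers, entered no test. No column belonged to other samples. Of the 14701 genes, 14654 were placed by identifier on the RefSeq annotation of GRCm38.p6, and 99.4% of 13866 genes on main chromosomes had the same start to 3 digits as the deposited tables. Gene Ontology and KEGG terms were those in the deposited tables.

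Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. The filterByExpr filter (minimum count 10) kept 11423 genes and left out 3278. TMM factors, 1.016 to 1.033 in controls and 0.9717 to 0.9816 in treated libraries, scaled the libraries, and the quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest) compared interferon-gamma with control. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. CPM are counts per effective library size, and log2 CPM used a prior count of 2. The highest CPM of the epithelial identity genes and the range of Col1a1 over libraries were taken on total counts instead. Standard errors of log2 changes were computed from the replicates' log2 CPM with that prior count, not from the edgeR fit. The prior count draws low values together, so these errors can be too small for genes of few counts. Where a group's total was 3 counts or fewer, a ratio of depth-scaled totals is given with an exact 95% binomial interval, which covers counting error only.

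Before the data were examined, 25 gene lists, the tests, the alternatives and the rule for naming genes were fixed. The rule names 20 chosen genes, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 1 CPM and separated groups, up to 4 genes of smallest adjusted p in each list, and the 3 most abundant genes. Of the 20 chosen genes, 1 is not reported here. Other genes are said to be named after their values were seen. A few genes sit in more than 1 list. Of the 25 lists, 19 had at least 3 tested members and went to camera (limma 3.58.1, preset correlation 0.01) on voom values, adjusted over the 19, with camera at an estimated correlation and fry as checks. Camera called 13 lists, of which the interferon-gamma pathway, GTPase, MHC class I, chemokine, antiviral and cell death lists also passed with an estimated correlation. That setting is not a check of correlation alone, since adjusted p also rose where the estimate lay under the preset. The interferon-gamma pathway, at -0.04, went from 5.49e-16 to 0.00796, and the antiviral list, at -0.03, from 4.71e-29 to 0.00419. The enterocyte, secretory and leukocyte lists had too few tested members for camera, the epithelial identity and endothelial lists had none, and the tables analysed here hold no row for the 13 protein-coding genes of the mitochondrial genome. A comparison of long noncoding RNA was not run.

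Alternatives were DESeq2 1.42.0 and limma-voom tests, median-of-ratios (RLE), upper-quartile and total-count scaling, no filter, a filter of at least 1 CPM in 3 samples, robust=FALSE, a threshold of 0.01, glmTreat against folds of 1.5 and 2, the replicate number as a block, and each library left out in turn. Added after the data were examined were a fit without genes that share reads, total counts taken without the genes that rose at least 2-fold, left-out libraries and the other scalings for genes named outside the rule, hypergeometric tests of terms of 10 to 500 genes against the tested annotated genes, and 10000 permutations of gene order along the chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, terms and figures.

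Depth was even, with 17490689 to 18678543 counts per library, and the 10 most abundant genes took 4.43% to 4.76% of them. Tested on simulated data of this depth and spread with 50 genes per fold change, edgeR recovered 68% of genes changed 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 5.4% of 186 calls were false. In the simulation 5 of 5 shifted lists and 0 of 5 unshifted lists were called by camera. Simulated genes were drawn independently and lists at random, so neither result covers correlated genes. The glycolysis list, for 1, had an estimated correlation of 0.5 in the data. Far fewer genes changed in the simulation than in the data. The median log2 fold change over all tested genes was 0.009.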

Results

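RNA was sequenced from 6 samples of IEC 4.1, a mouse intestinal epithelial line by its label. Untreated controls (replicates 2, 3 and 4) were set against samples given interferon-gamma at 10 ng/ml for 6 h (replicates 1, 2 and 4), n = 3 per group. Interferon-gamma is a cytokine of activated T cells and natural killer cells that signals through the kinases Jak1 and Jak2. The control libraries held 18516091, 18288259 and 18357549 estimated counts over 14701 protein-coding genes, and the treated libraries held 18322228, 18678543 and 17490689. Spearman's correlation across genes, which are not independent replicates, was 0.994 to 0.996 between libraries of a group and 0.976 to 0.978 between libraries of different groups. The first principal component held 88.8% of the variance and separated the groups. The comparison asks which genes change in this line within 6 h of interferon-gamma.

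With interferon-gamma, interferon-inducible GTPases, MHC class I genes, chemokines and antiviral genes rose together, and nearly all of the changes above 4-fold were rises. Irf1 rose from 95.4 ± 5.42 to 1140 ± 14.4 CPM (mean ± SD, n = 3 per group), and Gbp2b rose from 6.3 to 4060 CPM. The T cell chemoattractant Cxcl10 rose from 29.7 to 1330 CPM, the inducible nitric oxide synthase Nos2 from 8.28 to 518 CPM and Cd274, which encodes the ligand PD-L1, from 3.1 to 127 CPM. Falls were smaller: Zfp469 fell from 25.3 to 4.03 CPM, and the transcription factor Myc from 134 to 88.1 CPM.

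Of 11423 genes tested with edgeR, 2278 rose and 2069 fell at an adjusted p under 0.05, 38.1% of those tested. At least 2-fold changes numbered 460 rises and 120 falls, and at least 4-fold changes 227 rises and 11 falls. Rises of at least 10-fold numbered 116, and 30 genes rose at least 100-fold, 13 of them from a total of 3 or fewer counts in the controls. Most calls were small: 1818 rises and 1949 falls stayed under 2-fold. The balance of small calls depended on scaling, with 1775 rises and 2823 falls after upper-quartile scaling and 1644 rises and 3124 falls on total counts. The genes that rose at least 2-fold held 0.94% to 0.96% of the control counts and 5.44% to 5.48% of the treated counts. No gene in the tables was at 0 in all 3 controls while 673 were at 0 in all 3 treated libraries, so a gene silent in controls has no values here and the rises are counted only among genes detected in a control.

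**Figure D1:**
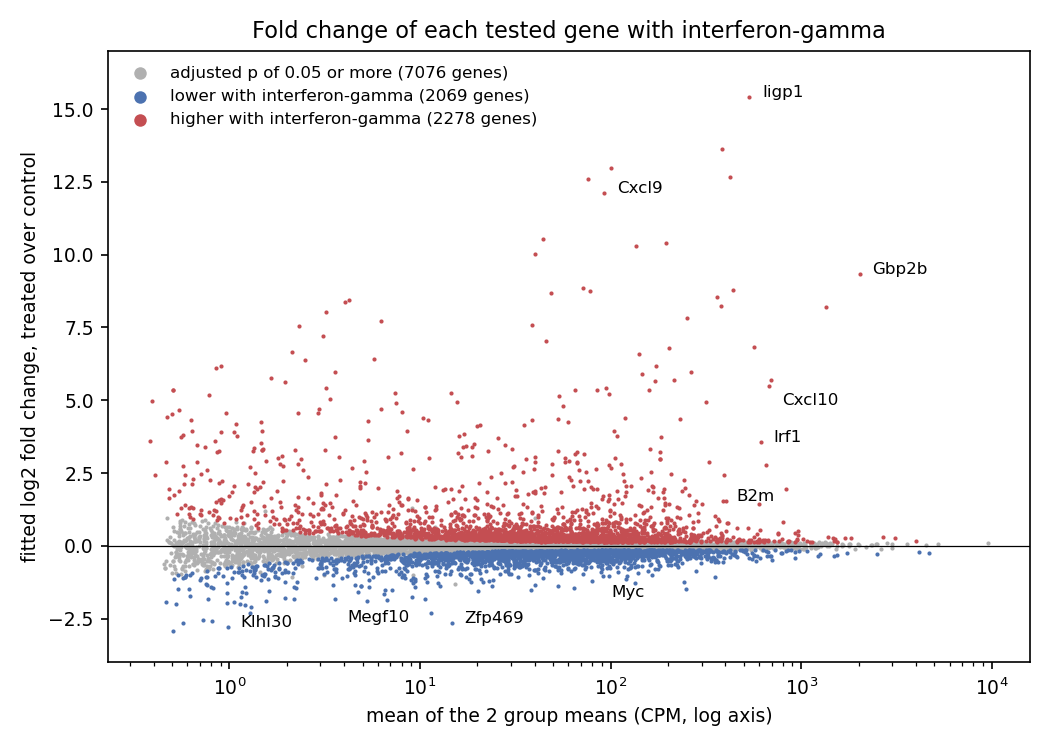
Each point is 1 of the 11423 tested genes, with the mean of the 2 group means (CPM, log axis) on the x axis and the log2 fold change of interferon-gamma (n = 3) over control (n = 3) on the y axis. The 2278 genes that rose reach far larger changes than the 2069 that fell.

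Genes of the interferon-gamma pathway itself rose widely, 17 of 19 tested, with a median log2 fold change of 2.98 (camera adjusted p = 5.49e-16, and 0.00796 with an estimated correlation). Irf1 (NCBI Gene 16362, chromosome 11, 53770014 to 53778374), an early transcription factor of the interferon response, rose by 3.58 ± 0.048 on the log2 scale (± SE between replicates, n = 3 per group, adjusted p = 6.06e-22). Stat2, a few of whose reads are shared with another gene, rose by 3.76, Stat3, named after its values were seen, by 2.47 and the feedback inhibitor Socs1 by 3.01 ± 0.092, from 12.8 to 103 CPM. The receptor chains moved the other way: Ifngr1 fell from 65.8 to 55.5 CPM (log2 -0.24, adjusted p = 0.00444) and Ifngr2 from 97.4 to 77.4 CPM (log2 -0.33, adjusted p = 3.87e-05), and these were the 2 members that fell. The count adjusted over the list alone was the same. Among those that rose, Jak1, named after its values were seen, rose by only 0.17 on the log2 scale (adjusted p = 0.0105). Its call was lost with upper-quartile scaling (adjusted p = 0.0677), on total counts (0.117) and without control replicate 4 (0.106). The tables analysed here hold no row for Irf8.

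All 19 tested interferon-inducible GTPases rose, also when adjusted over the list alone, with a median log2 fold change of 8.53 (camera adjusted p = 7.62e-34, and 0.00924 with an estimated correlation). These GTPases act on the vacuoles of intracellular bacteria and parasites. Gbp2b (chromosome 3, 142594816 to 142619179) rose by 9.33 ± 0.114 on the log2 scale, Gbp2 (chromosome 3, 142620663 to 142638008) by 8.21 ± 0.022, from 9.09 to 2690 CPM, and Igtp by 8.80 ± 0.074, from 1.96 to 877 CPM. Irgm1, already at 19.9 CPM in controls, rose by 4.94 to 611 CPM. Iigp1 had a total of 1 count in the 3 controls and 56655 in the 3 treated libraries, a depth-scaled ratio of 60300 (95% interval 10800 to 2380000). Gbp2b, Gbp2, Gbp4 and Igtp had non-whole counts, a mark of reads divided between similar genes, so their single-gene values are less certain than that of Irgm1.

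**Figure D2:**
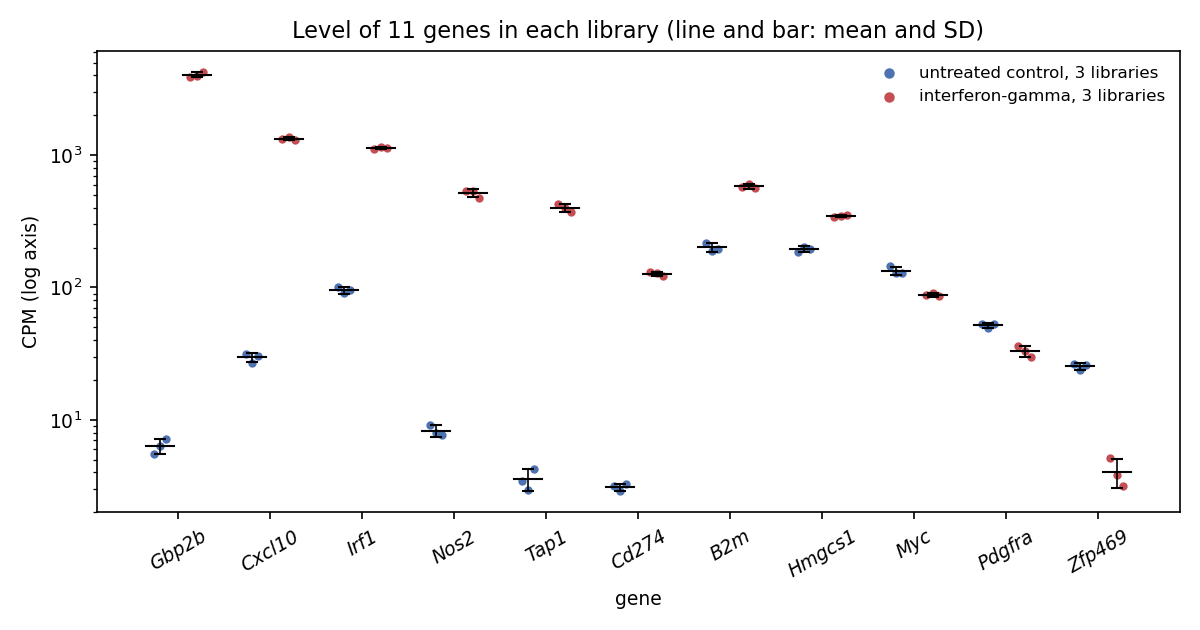
Each point is 1 library, with 11 genes on the x axis and CPM on a log y axis, for control and interferon-gamma (n = 3 each, line and bar for mean and SD). Gbp2b went from 5.48, 6.29 and 7.12 CPM to 3910, 3980 and 4270 CPM, and Myc from 145, 128 and 128 CPM to 87, 91.3 and 86 CPM.

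For antigen presentation to CD8 T cells, 20 of 23 tested MHC class I genes rose, also when adjusted over the list alone, with a median log2 fold change of 1.89 (camera adjusted p = 5.19e-26, and 0.0131 with an estimated correlation). The peptide transporter Tap1 rose by 6.81 ± 0.162 on the log2 scale, from 3.55 to 399 CPM (adjusted p = 3.4e-23), and the immunoproteasome subunit Psmb9 by 7.03 ± 0.215, from 0.69 to 90.8 CPM. The abundant B2m and H2-K1 rose less, from higher levels: B2m went from 201 to 581 CPM (log2 1.53 ± 0.069) and H2-K1, whose reads are shared with similar genes, from 231 to 474 CPM (log2 1.04 ± 0.06). Nlrc5, the transactivator of class I genes, rose by 5.37 ± 0.266, from 3.96 to 165 CPM. The 3 members past no threshold were Calr, Canx and Pdia3, general chaperones of the endoplasmic reticulum named after their values were seen, at log2 0.08, 0.06 and 0.06, with Canx and Pdia3 at -0.01 on total counts.

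Of 12 MHC class II genes, 5 were too low to be tested and 3 had no values here. A gene silent in controls has no values here, so the list cannot show class II genes switched on from nothing. Of 4 tested, 2 rose, also when adjusted over the list alone, with a median log2 fold change of 0.29 (camera adjusted p = 0.0959) that was 0.08 with no low-count filter. Ciita, the class II transactivator, rose from a total of 3 counts in controls to 173 in treated libraries, a ratio of 61.4 (95% interval 20.6 to 300). H2-DMa rose from 4.23 to 5.78 CPM (log2 0.45, adjusted p = 0.0119). The log2 fold change of H2-DMa was 0.39 without control replicate 3 (adjusted p = 0.0523) and 0.34 without treated replicate 1 (adjusted p = 0.0949), so that call rests on those libraries. Cd74, the invariant chain, was at 12.8 and 13.8 CPM (log2 0.11, adjusted p = 0.369), and H2-DMb1 had log2 0.13 (adjusted p = 0.524).

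Among chemokines and cytokines 13 of 16 tested genes rose, 14 when adjusted over the list alone, with a median log2 fold change of 1.37 (camera adjusted p = 8.32e-14, and 0.00833 with an estimated correlation). Cxcl10 (chromosome 5, 92346638 to 92348889) rose by 5.49 ± 0.067 on the log2 scale (adjusted p = 5.67e-24), and its relative Cxcl9 went from a total of 2 to 9833 counts, a ratio of 5230 (95% interval 1450 to 43200). The monocyte chemoattractants Ccl2 and Ccl7 rose by 1.45, from 323 to 884 CPM, and by 1.74, from 119 to 399 CPM. Il6, named after its values were seen, rose from 0.496 to 6.65 CPM.

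Antiviral genes usually linked to type I interferon rose in 24 of 25 tested members, also when adjusted over the list alone, with a median log2 fold change of 3.95 (camera adjusted p = 4.71e-29, and 0.00419 with an estimated correlation). Parp14 rose by 5.70 ± 0.126 on the log2 scale, from 8.06 to 421 CPM, Oasl2 by 5.20, from 5.2 to 191 CPM, and Parp9 by 4.38. Oasl1, named after its values were seen, had log2 -0.01 (adjusted p = 0.982) and ran from -0.10 to 0.03 over left-out libraries, above 0 without control replicate 4 or treated replicates 1 or 4 (0.03 each).

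Antimicrobial effectors rose in 10 of 11 tested members, with a median log2 fold change of 2 (camera adjusted p = 8.3e-13, and adjusted p = 0.052 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell, the metal transporter Slc11a1, named after its values were seen (log2 -0.28). Slc11a1 also passed over all genes with RLE (adjusted p = 0.0496), upper-quartile (0.0221) or total-count scaling (0.016), and without control replicate 3 (0.0413) or treated replicate 1 (0.0326). Nos2 (chromosome 11, 78920787 to 78960226) rose by 5.97 ± 0.101 on the log2 scale (adjusted p = 3.57e-23). Wars, a tryptophan tRNA synthetase, rose from 78.4 to 581 CPM and Samhd1, which depletes nucleotides needed by viruses, from 168 to 1140 CPM. The tables analysed here hold no row for Ido1.

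Cell death genes rose in 16 of 23 tested members and fell in 3, also when adjusted over the list alone, with a median log2 fold change of 1.04 (camera adjusted p = 1.07e-08, and 0.0111 with an estimated correlation). The nucleic acid sensor Zbp1 rose by 7.60 ± 0.196 on the log2 scale, from 0.389 to 76.7 CPM, and Xaf1 by 5.13, both also counted among the antiviral genes. Zbp1 had 8, 5 and 9 counts in the controls, so its standard error is uncertain. The death receptor Fas rose by 3.32, from 5.52 to 55.2 CPM (adjusted p = 2.66e-18), and the inflammatory caspase Casp4 by 3.47. The 3 that fell, named after their values were seen, were Bcl2 (log2 -0.44) and Bcl2l1 (log2 -0.38), which encode survival proteins, and the pore-forming Gsdme (log2 -0.37).

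Ligands that stimulate or restrain T cells rose in 5 of 7 tested genes and fell in 1, also when adjusted over the list alone, with a median log2 fold change of 0.69 (camera adjusted p = 0.00375, and adjusted p = 0.0668 with an estimated correlation). Cd274 (chromosome 19, 29362107 to 29388095) rose by 5.35 ± 0.061 on the log2 scale (adjusted p = 3.06e-22), and Tnfrsf14, a partner of BTLA whose reads are shared with another gene, by 3.19. Lgals9 rose by 0.69. Cd276, which fell by 0.31 on the log2 scale, was named after its values were seen.

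NF-kappaB pathway members and targets rose in 12 of 17 tested genes and fell in 2, or 3 when adjusted over the list alone, with a median log2 fold change of 0.36 (camera adjusted p = 0.000146, and adjusted p = 0.0885 with an estimated correlation). Nfkbiz rose by 1.86 on the log2 scale, from 52.3 to 189 CPM, Sod2 by 1.64, from 92.9 to 289 CPM, Bcl3 by 1.33, and the adhesion molecule Vcam1 by 0.78, from 304 to 522 CPM.

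**Figure D3:**
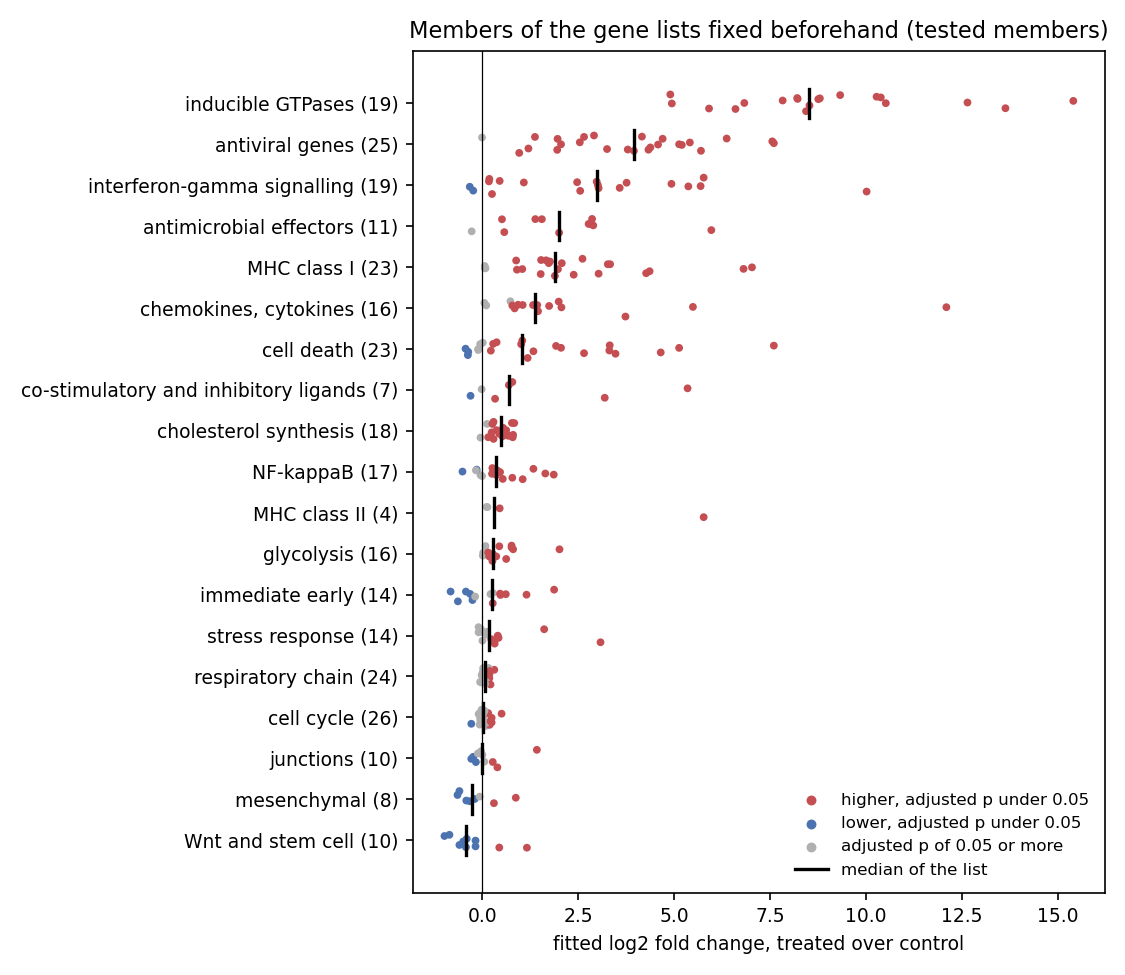
Each point is 1 tested gene and each black line the median of its list, with the log2 fold change of interferon-gamma over control on the x axis (n = 3 per group). Medians of the 19 lists shown run from 8.53 for the interferon-inducible GTPases to -0.42 for Wnt target and stem cell genes.

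Zfp469 (chromosome 8, 122043123 to 122272650) fell by 2.65 ± 0.2 on the log2 scale (adjusted p = 6.87e-14), and the engulfment receptor Megf10 (chromosome 18, 57133090 to 57297467) fell from 19 to 3.81 CPM (log2 -2.32 ± 0.254, adjusted p = 7.38e-12). The R-spondin receptor Lgr6 fell from 8.35 to 2.23 CPM (log2 -1.90 ± 0.196, adjusted p = 2.07e-09). The receptor kinase Ret (1.4 to 0.223 CPM, log2 -2.59) and the integrin subunit Itgb3 (1.68 to 0.433 CPM, log2 -1.94) fell from low levels. Klhl30 fell by 2.78 ± 0.321 from a low level, 1.72 to 0.245 CPM.

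Wnt target and intestinal stem cell genes fell in 8 of 10 tested members and rose in 2, also when adjusted over the list alone, with a median log2 fold change of -0.42 (camera adjusted p = 0.00339, and adjusted p = 0.0668 with an estimated correlation). Myc (chromosome 15, 61985341 to 61990361) fell by 0.60 ± 0.066 on the log2 scale (adjusted p = 3.03e-08). The transcription factor Sox9 fell from 11 to 6.03 CPM (log2 -0.86, adjusted p = 6.65e-06), Cd44 from 399 to 300 CPM (log2 -0.41), and Ephb3 from 33.2 to 23.4 CPM (log2 -0.50). Named after their values were seen, Notum (log2 -0.99) and Znrf3 (log2 -0.43), which restrain Wnt signalling, also fell, while the feedback inhibitor Axin2 (log2 1.16, adjusted p = 0.0172) and the receptor Ephb2 (log2 0.44) rose. The Axin2 call rests on low counts and was lost without treated replicate 4 (log2 0.69, adjusted p = 0.186) or control replicate 3 (log2 1, adjusted p = 0.0606). The tables analysed here hold no row for Lgr5, Ascl2 or Olfm4. Epithelial identity genes were near the floor in all libraries, so these falls do not show a change in crypt or stem cells.

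Of the mesenchymal markers, 5 of 8 tested fell and 2 rose, also when adjusted over the list alone, with a median log2 fold change of -0.26 (camera adjusted p = 0.0577). The list passed camera without control replicate 3 (adjusted p = 0.0488), treated replicate 1 (0.0471) or treated replicate 2 (0.0477), and with a replicate block (0.0354). It also passed fry (adjusted p = 0.00654). Pdgfra fell from 51.8 to 33 CPM (log2 -0.65, adjusted p = 1.23e-07), Pdgfrb from 88.6 to 58.6 CPM and Col3a1 from 340 to 254 CPM. Dcn rose from 7.56 to 13.8 CPM. Named after their values were seen, Vim rose from 2390 to 2950 CPM (log2 0.30, adjusted p = 2.63e-05) and Col1a1 fell from 1660 to 1320 CPM (log2 -0.33, adjusted p = 0.000277). Lum, also named after its values were seen, was near the floor at 0.0353 and 0.112 CPM, and the tables analysed here hold no row for Thy1. Epithelial identity genes were near the floor in both groups: 8 of 12 had values, none above 0.547 CPM in any library, and none was tested.

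**Figure D4:**
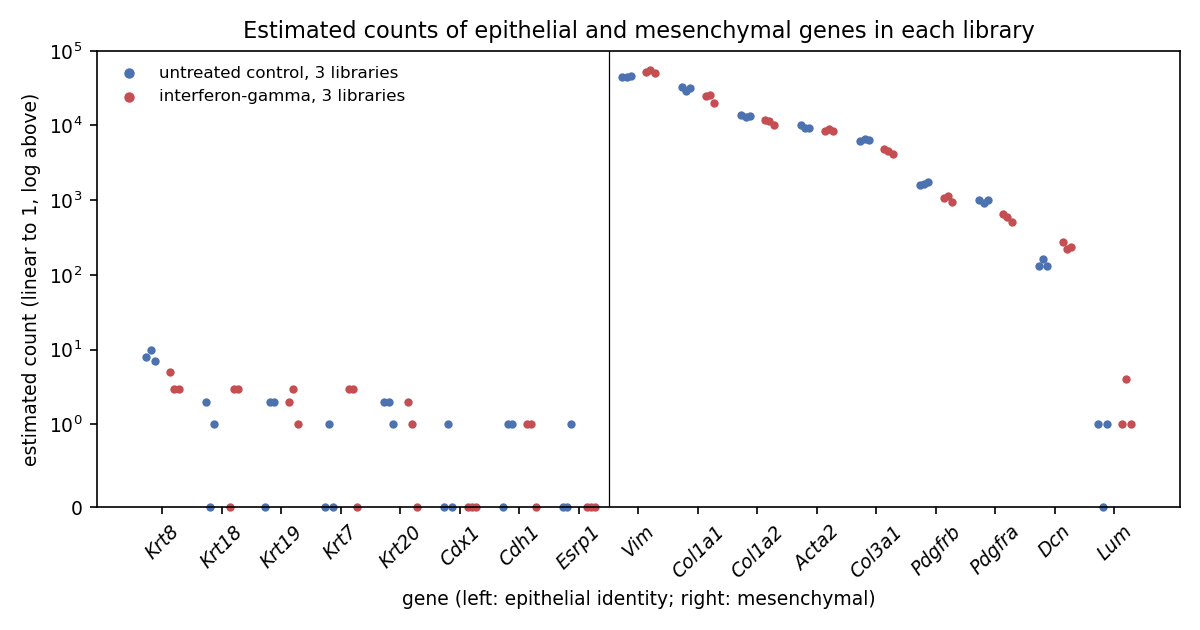
Each point is 1 library (control and interferon-gamma, n = 3 each), with estimated counts on the y axis and genes on the x axis, 8 epithelial identity genes on the left and 9 mesenchymal genes on the right. Krt8 had 8, 10 and 7 counts in controls and 5, 3 and 3 in treated libraries, far under the collagen genes, while the mesenchymal gene Lum had 0 to 4 counts.

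Of the other cell type markers, few were tested: 1 of 10 enterocyte, 2 of 19 secretory and 2 of 11 leukocyte genes. Such few genes do not show that these cell types were present. The enterocyte gene Anpep fell (log2 -0.44, adjusted p = 0.00471), as did Dclk1 (log2 -0.41, adjusted p = 0.00182), a tuft cell marker, while the hormone gene Cck had log2 -0.35 (adjusted p = 0.365). The leukocyte markers Cd14 (log2 -0.17, adjusted p = 0.0961) and Cd68 (log2 -0.10, adjusted p = 0.758) passed no threshold. The log2 fold change of Cd14 was -0.22 with upper-quartile scaling (adjusted p = 0.0272) and -0.24 on total counts (adjusted p = 0.0177), and the log2 fold change of Cd68 was 0.01 without control replicate 2. The calls in these lists were the same when adjusted over each list alone. No endothelial marker was tested.

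Sterol synthesis and uptake genes rose in 16 of 18 tested members, also when adjusted over the list alone, with a median log2 fold change of 0.48 (camera adjusted p = 2.29e-09, and adjusted p = 0.052 with an estimated correlation). Hmgcs1 rose by 0.83 ± 0.042 on the log2 scale, from 195 to 346 CPM (adjusted p = 2.26e-11), Idi1, with shared reads, by 0.80, Cyp51 by 0.77 and Sqle by 0.65 ± 0.009. Glycolysis and glucose uptake genes rose in 13 of 16 tested members, also when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 5.88e-07, and adjusted p = 0.194 with an estimated correlation). Hexokinase Hk2 rose by 2.01 ± 0.107, from 31.7 to 127 CPM (adjusted p = 1.31e-15), and the glucose transporter Slc2a1 by 0.80, from 144 to 250 CPM.

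Nuclear-encoded respiratory chain genes rose in 7 of 24 tested members, also when adjusted over the list alone. The median log2 fold change was 0.07 (camera adjusted p = 0.105), it was -0.01 on total counts, and the list passed without control replicate 2 (adjusted p = 0.0111) or treated replicate 1 (adjusted p = 0.0405). Ndufa1 rose by 0.31 (adjusted p = 0.000985).

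Cell cycle genes had 6 of 26 risen and 1 fallen, also when adjusted over the list alone, with a median log2 fold change of 0.02. As a list they did not differ from other genes by camera (adjusted p = 0.454). Fry, which does not compare a list with other genes, called them (adjusted p = 0.00599). The median was -0.04 with upper-quartile scaling, -0.05 on total counts and 0 without control replicate 4. Top2a, the DNA topoisomerase of dividing cells, rose from 794 to 1130 CPM (log2 0.50, adjusted p = 3.75e-08). Junction genes had 3 of 10 risen and 3 fallen, also when adjusted over the list alone, with a median of -0.02 but a mean of 0.13 (camera adjusted p = 0.985, in the upward direction), and the median was 0 without control replicate 3 and 0.01 without control replicate 4. F11r, a tight junction protein, rose by 0.39, and plakoglobin Jup fell by 0.24 (adjusted p = 0.012).

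Unfolded protein and integrated stress response genes rose in 7 of 14 tested members, also when adjusted over the list alone, with a median log2 fold change of 0.17 (camera adjusted p = 0.0186, and adjusted p = 0.0904 with an estimated correlation), or 0.1 on total counts. Atf3 rose by 3.08, from 3.93 to 33.4 CPM, and Trib3 by 1.61. Immediate-early genes went both ways, 6 of 14 risen and 5 fallen, or 6 fallen when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.443) that was 0.15 without control replicate 3. Zfp36, which destabilises cytokine transcripts, rose by 1.87, Jun rose by 0.61, and Ier2 fell by 0.64 on the log2 scale.

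The most abundant transcripts moved little. Eef1a1, the largest, was at 9250 and 9820 CPM (log2 0.09, adjusted p = 0.228), though it passed without control replicate 2 (log2 0.13, adjusted p = 0.0409). Hsp90ab1 was at 5150 and 5340 CPM (log2 0.05, adjusted p = 0.41, but 0 with upper-quartile scaling and -0.02 on total counts), and Actb fell from 5050 to 4320 CPM (log2 -0.23, adjusted p = 0.000926). Eef1a1 and Actb share reads with similar genes.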

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

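All tests in this part were chosen after the result was seen. The deposited TPM values, which the comparison of the groups does not use, sum to a fixed total when every gene is listed. In the treated libraries the sums were 189.3, 177.0 and 180.7 TPM short of it, a mean of 182.4 (SD 6.3, n = 3), so a signal lay outside the listed genes, above the control level, where the largest deviation was 0.43. Rounding of the values would give both groups a like shortfall, which 182.4 against 0.43 does not bear out. The numbers are consistent with tables that hold only genes with a count in a control: 0 genes were at 0 in all 3 controls and 673 were at 0 in all 3 treated libraries, with no control total above 22.23 among these. Genes switched on from nothing by interferon-gamma could then account for the missing signal, and which genes these were was not analysed here.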

How the results depend on the processing

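The alternatives used edgeR or camera unless named, and the fits without risen genes in the totals or without shared reads, and all settings for genes named outside the rule, were chosen after the result was seen. Over the alternatives, the 4 gene counts stayed within 1.5 times of their value except in 2 cases: 3124 genes fell on total counts, which returned to 2090 when the genes that rose at least 2-fold were kept out of the totals, and 41 genes were at least 2-fold lower in glmTreat against a fold of 2, a stricter test by construction. Leaving out 1 library gave 1851 to 2187 rises, 1710 to 2025 falls, and 462 to 475 and 117 to 144 changes of at least 2-fold. DESeq2 gave 1898 and 1763, limma-voom 2263 and 2055, and robust=FALSE 2264 and 2053, and these 3 give no gene list value. Without genes that share reads, 1948 rose and 2024 fell of 10234.

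Directions turned only in results near 0. The log2 fold change of Hsp90ab1 was 0 with upper-quartile scaling and -0.02 on total counts, and the log2 fold change of Cd68 was 0.01 without control replicate 2 and ran from -0.26 to 0.01 over left-out libraries. Cell cycle genes had a median of -0.04 with upper-quartile scaling, -0.05 on total counts and 0 to 0.03 over left-out libraries (0 without control replicate 4). Respiratory chain genes had -0.01 on total counts and 0.04 to 0.1 over left-out libraries, passing without control replicate 2 (adjusted p = 0.0111) or treated replicate 1 (0.0405). Junction genes had 0 with no filter and -0.05 to 0.01 over left-out libraries (0 without control replicate 3, 0.01 without control replicate 4). The MHC class II median was 0.08 with no filter, and the immediate-early median 0.15 without control replicate 3. For all of these the cause was not tested.

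With an estimated correlation, medians being the same, camera no longer called antimicrobial effectors (2), T cell ligands (0.69), NF-kappaB genes (0.36), Wnt and stem cell genes (-0.42), sterol synthesis (0.48), glycolysis (0.28) and stress response genes (0.17), and the cause was not tested. The estimated correlation was -0.03 for T cell ligands, 0 for Wnt and stem cell and -0.02 for stress response genes. These lie under the preset 0.01, so this setting lost calls even where correlation was no higher. It was higher for antimicrobial effectors (0.31), NF-kappaB genes (0.09), sterol synthesis (0.14) and glycolysis (0.5). Stress response genes (0.17, adjusted p = 0.0186) also missed a threshold of 0.01. Fry, which does not compare a list with other genes, called MHC class II (0.29, adjusted p = 0.00146), cell cycle (0.02, 0.00599), immediate-early (0.24, 0.00967) and mesenchymal genes (-0.26, 0.00654). Mesenchymal genes ran from -0.31 to -0.21 over left-out libraries and passed without control replicate 3 (0.0488), treated replicate 1 (0.0471) or treated replicate 2 (0.0477), the cause was not tested.

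The samples share only the numbers 2 and 4, and the labels name no shared culture, so they were not treated as paired. Deviations from the group means correlated at 0.322 and -0.123 between same-number samples. Between samples of different numbers they ran from -0.379 (control replicate 3 with treated replicate 2) to 0.407 (control replicate 3 with treated replicate 4). The numbers thus do not mark the most similar samples. With a replicate block 2133 genes rose and 1793 fell, and mesenchymal genes passed camera (-0.32, adjusted p = 0.0354). Control replicate 3 and treated replicate 1 have no counterpart of the same number, so the blocked contrast rests on replicates 2 and 4 alone. Pseudocount alternatives, meant for values other than counts, were not run. Genes of a few counts per library, such as the epithelial identity genes, are too shallow here to show a change.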

Other observations

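All tests in this part, except the 2 tests of causes for neighbouring genes, were chosen after the result was seen. Term tests place ribosome production among the genes that fell. In the KEGG ribosome biogenesis term 35 of 71 tested genes fell against 12.9 expected (hypergeometric adjusted p = 5.47e-07), 3 rose, and the median log2 fold change was -0.17. In the Gene Ontology term rRNA processing 67 of 149 fell against 27.2 expected (adjusted p = 8.75e-11), 19 rose, and the median was -0.13. Nop56, a nucleolar protein named like the other genes in this part after its values were seen, fell from 483 to 367 CPM (log2 -0.39, adjusted p = 1.24e-06). Cyclin D1 (Ccnd1) fell from 478 to 230 CPM (log2 -1.05, adjusted p = 3.72e-13), the Wnt transcription factor Lef1 from 16.5 to 4.67 CPM (log2 -1.82), the epidermal growth factor receptor Egfr from 65.7 to 39.3 CPM (log2 -0.74) and its ligands Areg from 12.9 to 5.91 CPM (log2 -1.13) and Hbegf from 56.3 to 34.2 CPM (log2 -0.72). The KEGG focal adhesion and MAPK terms held more falls than expected but went both ways. Focal adhesion had 58 of 156 lower against 28.3 expected (adjusted p = 1.38e-06), 31 higher and a median log2 fold change of -0.08, and MAPK signalling had 65 of 216 lower against 39.2 expected (adjusted p = 3.83e-04), 46 higher and a median of -0.04.

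Several complement genes rose with interferon-gamma. The Gene Ontology term for classical complement activation had 9 of 17 tested genes at least 2-fold higher against 0.7 expected (hypergeometric adjusted p = 3.53e-07). The broader KEGG complement and coagulation term had 12 of 30 at least 2-fold higher against 1.5 expected (adjusted p = 1.15e-07) and 4 at least 2-fold lower against 0.3 expected (adjusted p = 0.0558). C1s1 rose from 25.3 to 341 CPM (log2 3.75), C1ra from 41.1 to 194 CPM (log2 2.24), both with shared reads, and C3 from 73.2 to 152 CPM (log2 1.05).

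Genes changed at least 2-fold lay next to each other more often than in permuted orders. Among 11396 positioned tested genes, 459 genes at least 2-fold higher formed 115 adjacent pairs, against a mean of 18.5 and a highest value of 37 in 10000 permutations (permutation p = 1.0e-04, the smallest possible). The 118 genes at least 2-fold lower formed 9 pairs, against a mean of 1.2 and a highest value of 7 (permutation p = 1.0e-04). The longest run of risen genes, of 10, went from Trim7 to Ifi47 (chromosome 11, 48826138 to 49096987), and a run of 8 from Apol7a to Apol8 (chromosome 15, 77388217 to 77757062). Several runs held genes of the same family, such as the Apol run and runs of Gbp, Ifit and Oas genes. The permutations move each gene singly, so they cannot tell an effect of position from a response shared by related genes. For both tests of causes the prediction was written before the value was seen. Among the higher genes, reads shared between neighbouring copies could inflate pairs. Genes with whole counts in every library, ordered anew without the others, formed fewer pairs, 44 against a permuted mean of 12.1 and a highest permuted value of 25. Shared reads are thus not the whole cause, though a part of the excess could come from them. Overlapping gene models could also inflate pairs, but 107 pairs did not overlap, against a highest permuted value of 33.

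Epithelial identity genes were near 0 in all 6 libraries of a line labelled intestinal epithelium, beside abundant transcripts of some mesenchymal genes. Of 12 identity genes 8 had values, none above 0.547 CPM in any library, so missing entries do not account for the low levels of those 8. A mislabelled or mixed single library could not by itself give low levels in all 6. Col1a1 was at most 1.55 times as high in 1 library as in another, a range that includes its fall with interferon-gamma. That range cannot exclude a partly mixed library. Cells other than the labelled line in all libraries remain open, with a summed identity gene level of at most 1.12 TPM against 3880 to 4120 TPM for the mesenchymal list, since no library of the line from another source was used. Of the mesenchymal sum, Vim alone gave 2410 to 2910 TPM, while Lum had 0 to 4 counts per library and the tables analysed here hold no row for Thy1.

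Regrouping the 6 libraries gives 10 splits, too few for a share under 0.05. The real split called 4347 genes and was the 1 split to call that many, and the highest of the other splits by edgeR was 0, with 47 to 398 genes at an unadjusted p under 0.05 in those splits.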
